A study of Mus musculus with 2 samples.

How the data were processed

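Hindbrain tissue of mouse embryos at 12.5 days of gestation was studied by chromatin immunoprecipitation and sequencing with an antibody against histone H3 trimethylated at lysine 9 (H3K9me3), a mark of silent chromatin. Per the labels, the samples form 1 group of 2 biological replicates with no treatment, from pooled male and female embryos of the B6NCrl strain. Replicate 1 was made from 120 embryos and lists 2 technical replicates, and replicate 2 was made from 88 embryos and lists 1. The peak lists carry no read counts, so the sequencing depth is unknown and no counting interval on signal can be given.

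The authors deposited 4 peak lists in narrowPeak form on the mm10 assembly: 1 for each replicate, 1 called on both replicates pooled, and a replicated list that, per the deposited text notes, was derived from the pooled list and the replicates' lists. Those notes give a further file in common behind both replicates' lists and another one behind that of replicate 2 only, of a kind they do not state, so the overlap of the replicates is not that of fully independent calls. The labels name a possible control experiment. The aligner, the peak caller and their versions are not given in the sources used here. The form of the lists suits narrow peaks, whereas H3K9me3 often covers broad regions, so that a region can be divided into many peaks.

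The value read here as fold enrichment is the linear signal ratio that the authors deposited for each peak; that it is a fold over control is inferred from the file format and from the fold-over-control tracks that the notes mention. The −log10 p and −log10 q of each peak are those of the authors' caller, and every peak in the deposited lists has a −log10 p of at least 2.00. The deposited lists also hold a display score and the distance from the peak start to its summit, and neither was used. These values belong to the authors and were used only to describe, rank or filter peaks within a list. Coordinates are given from 1 on mm10, which has the sequence of GRCm38. Genes came from GENCODE M21 and the sequence from the soft-masked GRCm38 reference, whose chromosome names and lengths were checked against the peaks.

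Results rest on the replicated list unless another is named, and values of the 2 replicates are given as mean ± SD with n = 2. A replicated peak takes its borders from the pooled call, so a value of the replicated list can lie outside the range of the replicates. Peaks on chromosomes 1 to 19, X and Y were analysed, and peaks on unplaced and unlocalised scaffolds were left out of every comparison. A gene was called marked when its annotated body held at least 1 bp of a replicated peak. The background was the 21911 protein-coding genes on those chromosomes. The gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined.

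Replicates were compared by the share of peaks overlapping the other list by at least 1 bp, against 1000 rotations of one list by a random offset within each chromosome (one-sided permutation test). The overlap count was checked with bedtools 2.31.1. Annotation and sequence content were tested against 1000 rotations of the peaks (two-sided permutation tests, smallest p 0.002), with peak midpoints assigned in turn to a window of 1 kb either side of a transcription start site (TSS), exon, intron or none of these. Each of 24 gene lists was compared with the other protein-coding genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 24 lists. Beside it stand a rotation permutation test, which keeps the spacing of peaks and of clustered genes, and 10000 random lists matched on gene length in 20 bins, whose smallest p is 0.0002. Shares carry 95% Clopper-Pearson intervals, which treat genes as independent and are too narrow for clustered families. Within marked zinc finger genes, last exon and TSS window were compared by an exact McNemar test. Peaks at most 5 kb apart were joined into domains, and domains of at least 50 kb were set against 1000 random placements of the peaks within their chromosome. Median fold enrichment of peaks in list genes was compared with that in other protein-coding genes by 100000 permutations, adjusted over the lists with at least 2 peaks.

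Most lists were taken by symbol pattern or by fixed symbols: zinc finger, clustered protocadherin, olfactory and vomeronasal receptor, X-linked cancer-testis, Pramel, beta-defensin, keratin, cytochrome P450, serpin, histone, Hox, ribosomal protein, imprinted, germline, hindbrain regulator, pan-neural, housekeeping, H3K9 machinery, blood, endothelium and microglia, mesenchyme, forebrain and midbrain, and other-lineage genes. In all, 7 genes stood in more than 1 list, and 6 of the 79 cancer-testis genes lay off the X. Named genes are, for each list, up to 3 members (5 for the zinc finger and imprinted lists) with the most bases under replicated peaks among members that also overlap a peak of both replicates. Named too are the 10 protein-coding genes holding the peaks of highest fold enrichment, the protein-coding genes of the 5 longest domains, and every marked member of the H3K9 machinery, housekeeping, pan-neural and hindbrain lists if there are 5 or fewer. Imprinted genes that are not protein-coding are named with their values and were not tested.

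Alternatives were the pooled list, replicated peaks above the median fold enrichment, a −log10 q of at least 5, each replicate's list alone, overlaps of 50% of a peak or of both peaks, equal numbers of strongest peaks, autosomes only, a TSS window of 2.5 kb, at least 500 bp of peak, 5 kb flanks, a TSS window in place of the gene body, other backgrounds, last exons of at least 1 kb, joining distances of 1 kb and 10 kb, and −log10 p as the strength. The alternatives of the replicate overlap used 200 rotations. Added after the data were seen were the replicated peaks that overlap both replicates' lists, peaks of mostly or wholly single-copy sequence, gene families by symbol stem, peak position by list and TSS peaks on the X. A peak counted as mostly single-copy when most of 11 sampled 32-base sequences occurred once in the assembled chromosomes, and as wholly single-copy when all did. The gene list tests were tested on simulated data: in 20 simulated peak sets, with peaks added to 50% of 200 genes, the list was called in 100% of sets by Fisher's exact test and by length-matched lists, and in 100% of 5 sets by rotation, while 0.417% or fewer of unchanged random lists were called. In this simulation peaks were placed at random and lists were drawn at random over all genes. Its rate of false calls therefore does not cover clustered peaks or clustered families. Its rate of true calls holds for a list of 200 genes with this large an effect. Shorter changed lists, smaller effects and lists marked less often were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.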

Results

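H3K9me3 peaks were obtained from embryonic mouse hindbrain at 12.5 days, in 2 biological replicates of pooled embryos and 1 group. On the assembled chromosomes, the list of replicate 1 held 46873 peaks and that of replicate 2 held 59294, with 92116 in the pooled list and 29761 in the replicated list. With scaffolds included, peaks covered 13.4 Mb in replicate 1, 19.8 Mb in replicate 2 and 17.4 Mb in the replicated list. On the assembled chromosomes alone, replicated peaks covered 0.649% of the sequenced bases. Median peak width was 228 bp in replicate 1, 258 bp in replicate 2 and 464 bp in the replicated list, whose median fold enrichment was 3.03. A q below 0.05 was reached by 58.1% of the peaks of replicate 1, 73.2% of those of replicate 2 and 98.6% of replicated peaks. The design holds no second tissue or treatment, so the comparisons are those between replicates, and those between chromosomes, genes and gene groups within the tissue.

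The first comparison asked how far the replicates share their peaks. Of the peaks of replicate 1, 45.1% overlapped a peak of replicate 2, and of the peaks of replicate 2, 34.0% overlapped one of replicate 1. With an overlap of at least 50% of both peaks these shares were 23.3% and 18.5%. With both lists cut at a −log10 q of at least 5 they were 50.8% and 26.2%. Strong peaks were shared more often than weak ones. On the autosomes, 90.9% of the peaks of replicate 1 with a −log10 q of at least 5 were shared, and 31.4% of those with a −log10 q below 1. The same shares in replicate 2 were 81.5% and 18%. On the X chromosome 19.7% of the peaks of replicate 1 were shared, against 46.0% on the autosomes, and in replicate 2 the values were 23.9% and 34.3%. Over the clustered protocadherin genes on chromosome 18 (36910184 to 37861873), replicate 1 had 438 peaks, replicate 2 had 482 and the replicated list 351. Rotated lists shared 1.66% of peaks on average and 3.88% at most (one-sided permutation p = 0.001, the smallest that 1000 rotations can give). Shared bases made up 20.6% of the bases covered by either replicate. Across the 18789 replicated peaks found in both replicates, fold enrichment in the replicates correlated with a Spearman rho of 0.292 and a Pearson r of 0.393, across peaks, which are not independent replicates.

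The replicated list was then compared with the lists it came from. All 29761 replicated peaks were identical to a pooled peak, and they made up 32.3% of the pooled peaks and 51.2% of the pooled bases. Of the replicated peaks, 71.9% overlapped a peak of replicate 1, 89.0% one of replicate 2, and 63.1% (95% Clopper-Pearson interval 62.6% to 63.7%) one of both. A stricter overlap of at least 50% of the peak with both replicates was met by 37.1% of replicated peaks, and by 59.0% of the 11694 with a −log10 q of at least 5. Peaks found in replicate 2 but not replicate 1 numbered 7688, those in replicate 1 but not replicate 2 numbered 2613, and 671 overlapped neither list. Replicated peaks found in both replicates had a median fold enrichment of 3.19 and a median width of 539 bp, against 2.82 and 377 bp for the others.

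Chromosome 7 had the largest share of bases under H3K9me3 peaks and the sex chromosomes the smallest. It held 4743 replicated peaks, 15.9% of the list, at 33.4 peaks per Mb, and 2.12% of its sequenced bases were covered. That was 3.50 times the autosome median in the replicated list and 2.87 ± 0.00228 times (SD, n = 2) in the replicates' own lists. Chromosome 17 followed with 1.25% of bases covered (2.07 times the median) and chromosome 4 with 0.969% (1.60 times), and chromosome 14 was the lowest autosome with 0.341%. The X held 616 replicated peaks, 3.77 per Mb, and 0.193% of it was covered, 0.318 times the autosome median, with 0.436 ± 0.147 (SD, n = 2) in the replicates. The Y held 14 peaks. These shares count called peaks and do not measure the level of the mark. The pools held male and female embryos, and the lower copy number of the X and Y was not corrected for here. Nor is it known how reads that align to more than 1 place were treated. In both replicates chromosome 7 lay above every other chromosome and the X below every autosome. No test was made across chromosomes, because peaks cannot be rotated between them. Without replicate 2 the X stood at 0.540 times the median.

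**Figure D1:**
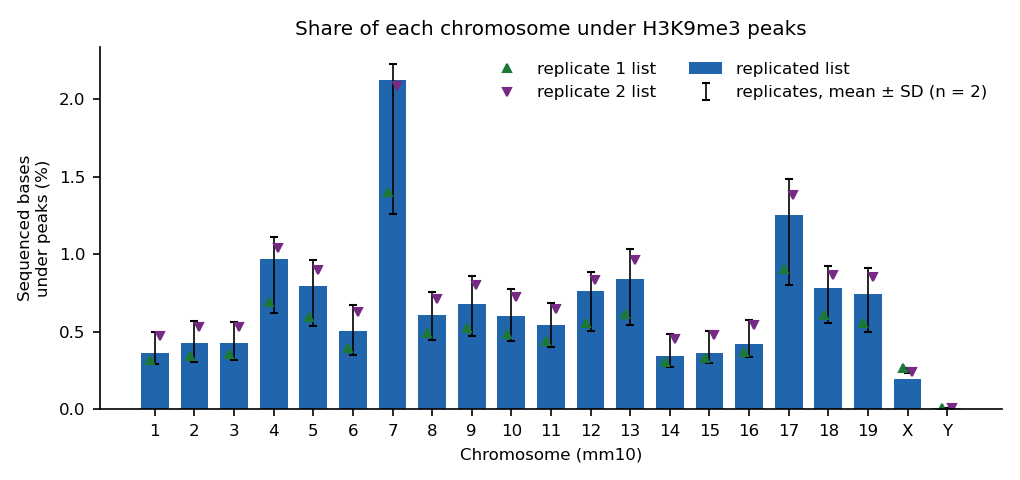
Bars show the percentage of sequenced bases of each mouse chromosome (mm10) under replicated H3K9me3 peaks, triangles the replicates' own lists, and error bars their mean ± SD (n = 2). Chromosome 7 reaches 2.12% in the replicated list, against 0.193% on the X.

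Relative to genes, H3K9me3 peaks lay mainly outside protein-coding genes. Peak midpoints fell outside them in 68.3% of cases (67.1% ± 1.25 in the replicates, SD, n = 2), against 58.1% for rotated peaks. Introns held 25% (26.1% ± 0.259) against 34.9% when rotated, and both differences passed a permutation test (p = 0.002 each, the smallest possible). Exons held 3.64% (3.44% ± 0.325) against 2.91%, 1.25 times the rotated share (permutation p = 0.004). The windows of 1 kb around a TSS held 911 peaks or 3.06% (3.34% ± 0.662) against 4.17%, 0.734 times the rotated share (permutation p = 0.002). The lower TSS share was not called without replicate 2, with a ratio of 0.932 (permutation p = 0.302). Nor was it with all annotated genes in place of protein-coding ones, with 1.09 (permutation p = 0.134). It was called for peaks overlapping both replicates' lists (0.752, permutation p = 0.004) and above the median fold (0.764, permutation p = 0.014). At a −log10 q of at least 5 it was called too (0.801, permutation p = 0.04). The higher exon share was not called in the pooled list, with a ratio of 1.02 (permutation p = 0.567), nor without replicate 1, with 1.11 (permutation p = 0.0539). For peaks overlapping both replicates' lists, above the median fold and at the stricter q it was 1.40, 1.43 and 1.56 (permutation p = 0.002 each).

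In sequence, the bases under replicated peaks were richer in G and C than rotated positions and held a similar share of soft-masked bases. GC content was 46.0% (46.8% ± 1.14 in the replicates, SD, n = 2) against 42.1% when rotated, a difference of 3.91 percentage points (permutation p = 0.002, the smallest possible). Soft-masked sequence, which marks interspersed and simple repeats, made up 34.2% of peak bases (33.8% ± 0.127) against 33.9% when rotated (permutation p = 0.643). Reads of recent repeats often align to more than 1 place, and how the authors treated them is not given in the sources used here. Of the replicated peaks 98.2% were of mostly single-copy sequence, against 85.0% when rotated. Rotated positions thus held more multi-copy sequence, and the similar soft-masked shares cannot tell whether the mark is enriched on repeats.

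Across the genome 3793 of 21911 protein-coding genes (17.3%) held a replicated peak, against 4070 for rotated peaks (permutation p = 0.00999). In the replicates' own lists 26.2% ± 0.487 of genes were marked (SD, n = 2), which is 5810 genes with replicate 2 alone, and 3993 genes were marked in both. Of the 24 gene lists, 6 were marked more often and 9 less often than other genes by Fisher's exact test. The zinc finger, clustered protocadherin, vomeronasal receptor, imprinted and germline lists were higher also against length-matched lists and rotated peaks, and none of the 9 lower lists was lower by all 3 tests.

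Zinc finger genes, most of which encode arrays of C2H2 fingers and many a KRAB repression domain, were among the groups marked most. Of 419 genes 169 carried a replicated peak, or 40.3% (95% interval 35.6% to 45.2%), and 49.4% ± 0.675 did in the replicates (SD, n = 2), against 16.9% of other genes in the replicated list. Peaks covered 24601 bp of Zfp936 on chromosome 7 (43114229 to 43192109), 31.6% of its body, and 23465 bp of Zfp943 on chromosome 17 (21962552 to 22071168), 21.6% of its body. Zfp873 on chromosome 10 (82048123 to 82064745) was covered over 87.3% of its body (77.7% ± 5.99 in the replicates), Zfp180 on chromosome 7 over 55.9% (44.9% ± 6.76) and Zfp981 on chromosome 4 over 46.9% (40.3% ± 3.70). The odds ratio of the list was 3.33 (Fisher's exact test, adjusted p = 3.52e-28). Length-matched random lists were marked at 13.3% and rotated peaks marked 17.9% of the list (permutation, adjusted p = 0.00959). With the TSS window in place of the gene body the list was not called, at an odds ratio of 1.52 (Fisher's exact test, adjusted p = 0.283).

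**Figure D2:**
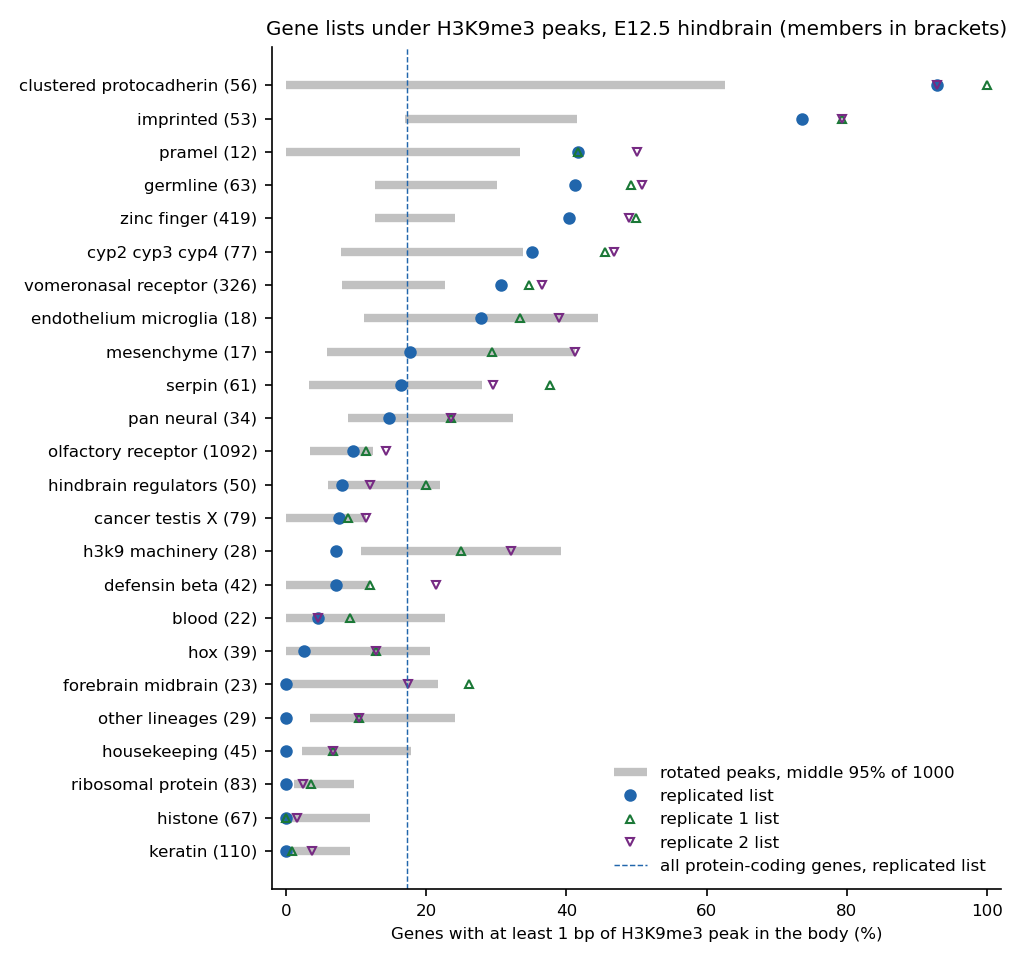
Each line is a gene list, with the percentage of its members that hold at least 1 bp of H3K9me3 peak in the replicated list (circle) and in each replicate's list (triangles). Grey bars span the middle 95% of 1000 rotations, and the dashed line is the 17.3% of all protein-coding genes; clustered protocadherin genes reach 92.9% and keratin genes 0%.

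Within zinc finger genes the mark lay over the 3′ end, where the finger array is usually encoded, and seldom over the promoter. Of 168 marked zinc finger genes with more than 1 exon, 114 (67.9%) had a peak over the last exon and 13 (7.74%) one in the TSS window. The last exons of Zfp873 and Zfp180 were covered in full, that of Zfp943 over 83.2%, that of Zfp936 over 62.3% and that of Zfp981 over 56.2%. In 106 genes only the last exon was covered and in 5 only the TSS window (exact McNemar test, p = 1.04e-25). Over all genes of the list, peaks covered 15.7% of last exon bases (13.2% ± 3.01 in the replicates, SD, n = 2), 4.44% of gene bodies (3.71% ± 0.798) and 0.887% of TSS windows (0.878% ± 0.0279). Other marked genes with more than 1 exon had a peak over the last exon in 10.03% of 3419 cases, an odds ratio of 18.9 for zinc finger genes (Fisher's exact test, p = 1.89e-66). The TSS window held a peak in 8.69% of these other genes, near the 7.74% of zinc finger genes. With windows of 2.5 kb the shares were 13.8% and 18.5%. A low TSS share was therefore not particular to zinc finger genes.

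**Figure D3:**
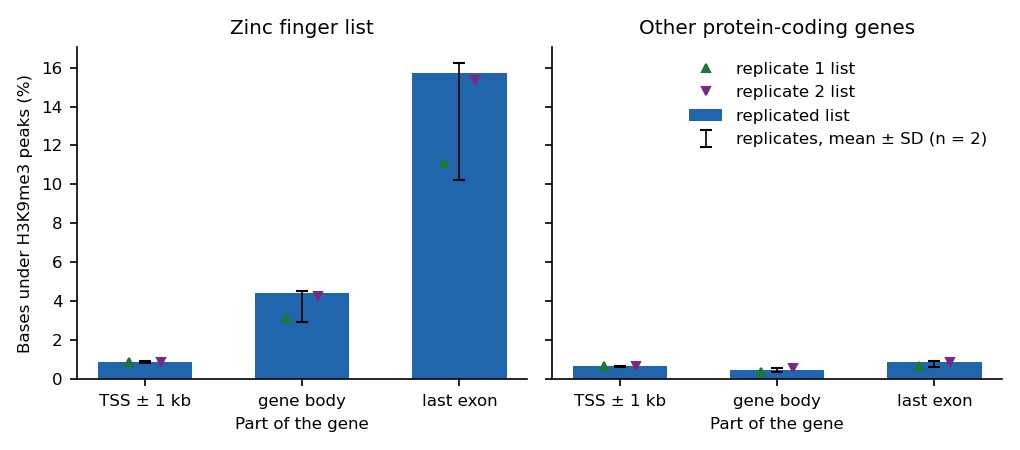
Bars show the percentage of bases under replicated H3K9me3 peaks in TSS windows, gene bodies and last exons of zinc finger genes (left) and of other protein-coding genes (right). Triangles are the replicates' own lists and error bars their mean ± SD (n = 2); last exons of zinc finger genes reach 15.7%, those of other genes 0.878%.

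The clustered protocadherins, cell adhesion proteins that give neurons a surface identity, were marked almost throughout. Of 56 genes 52 held a replicated peak, or 92.9% (95% interval 82.7% to 98.0%; 96.4% ± 5.05 in the replicates, SD, n = 2), and peaks covered 39.4% of the bases of the cluster genes. Pcdhga1 (chromosome 18, 37661793 to 37841873) was covered over 51.8% of its body (45.0% ± 4.62), Pcdhga2 over 52.5% (45.7% ± 4.66) and Pcdhga3 over 51.5% (45.0% ± 4.64). The region of the gene starts carried the mark: the TSS window was marked in 51 genes (91.1%; 88.4% ± 3.79 in the replicates). This window also reaches into the first exon, the variable one in alpha and gamma genes, so start and exon were not told apart. None of the 34 genes with more than 1 exon had a replicated peak over the last exon. The alpha and the gamma genes each share that exon as a constant part. The 4 genes without a replicated peak, named after their values were seen, were Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5, of the C type that lies nearest the constant exons; the list of replicate 1 had a peak in all 56 genes and the pooled list in 55. The odds ratio was 62.9 (Fisher's exact test, adjusted p = 7.80e-34), with 30.6% in length-matched lists and 32% for rotated peaks (permutation, adjusted p = 0.00959). By symbol stem, a grouping chosen after the results were seen, all 22 Pcdhb, 12 Pcdhga and 11 Pcdha genes were marked, but rotated peaks marked 3.65% of the Pcdhb (unadjusted permutation p = 0.002), 49.2% of the Pcdhga (0.729) and 65.4% of the Pcdha genes (1). The alpha and gamma gene bodies are nested and share peaks, so that the genes do not count as independent.

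**Figure D4:**
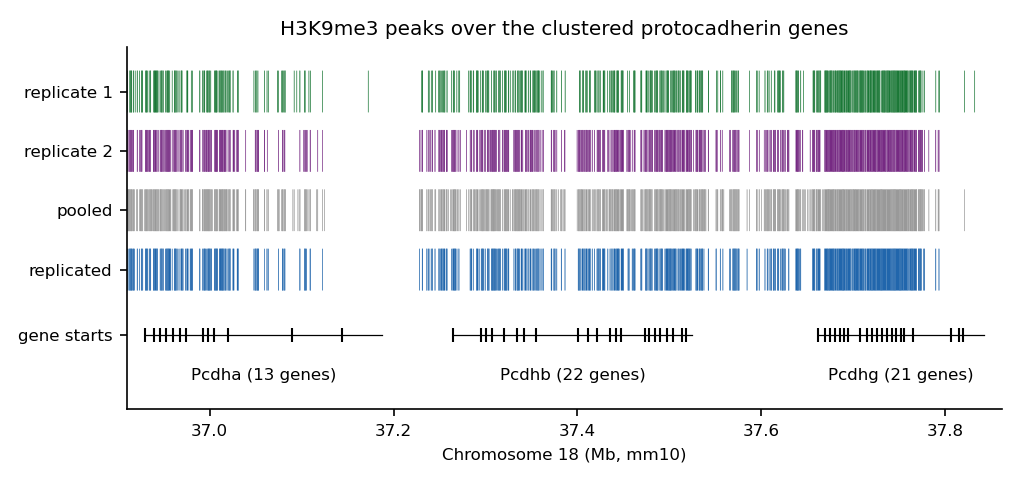
Map of chromosome 18 from 36910184 to 37861873 (mm10) with the peaks of each list as vertical bars and the starts of the clustered protocadherin genes below. The replicated list has 351 peaks in the window, and no replicated peak lies over the shared last exons of the alpha and gamma groups.

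Imprinted genes, expressed from 1 parental copy, were marked in 39 of 53 cases, or 73.6% (95% interval 59.7% to 84.7%; 79.2% in each replicate). Gnas, which encodes a stimulatory G protein subunit, had 10903 bp under peaks (chromosome 2, 174284320 to 174346744), 17.5% of its body (13.7% ± 3.03 in the replicates, SD, n = 2). Snrpn, of the locus lost in Prader-Willi syndrome, had 8922 bp, Kcnq1, a potassium channel gene, 7900 bp, Grb10, an adaptor of growth factor receptors, 5720 bp, and Trappc9 5667 bp. TSS windows were marked in 15 genes (28.3%; 31.1% ± 1.33 in the replicates), against 2.34% of other genes (Fisher's exact test, adjusted p = 8.99e-12). Some of these windows overlap, such as those of Peg3 and Usp29 and of Sgce and Peg10, so the genes do not count as independent. Among imprinted non-coding genes, Kcnq1ot1 had 6710 bp under peaks, Nespas 3859 bp, Airn 3548 bp, Rian 3028 bp, Meg3 2663 bp, Peg13 2651 bp and Zfp264 1616 bp, and H19 and Mirg had none in the replicated list or in the list of either replicate. Kcnq1ot1 lies within Kcnq1, Peg13 lies within Trappc9 and Nespas overlaps Gnas, so the same bases are counted for both genes. The odds ratio of the protein-coding members was 13.4 (Fisher's exact test, adjusted p = 2.48e-18), with 24.5% in length-matched lists and 28.8% for rotated peaks (permutation, adjusted p = 0.00959).

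Germline genes, which act in meiosis, in the piRNA pathway or in oocyte and testis, were marked in 26 of 63 cases, or 41.3% (95% interval 29.0% to 54.4%; 50% ± 1.12 in the replicates, SD, n = 2). Nlrp5, a maternal factor of the oocyte, had 26680 bp under peaks (chromosome 7, 23385889 to 23441922), 47.6% of its body (33.1% ± 9.18). Taf7l, a testis paralog of a general transcription factor subunit, had 1516 bp, with 970 bp in its TSS window, and Piwil1, a piRNA-binding Argonaute, had 1190 bp. The odds ratio was 3.37 (Fisher's exact test, adjusted p = 1.77e-05), with 19% in length-matched lists and 20.9% for rotated peaks (permutation, adjusted p = 0.00959).

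Large receptor and enzyme families were marked unevenly. Vomeronasal receptors, the pheromone receptors, were marked in 100 of 326 cases, or 30.7% (95% interval 25.7% to 36.0%; 35.6% ± 1.30 in the replicates, SD, n = 2), with 15250 bp in Vmn2r60, 9846 bp in Vmn2r59 and 9459 bp in Vmn2r53, all on chromosome 7. The odds ratio was 2.14 (Fisher's exact test, adjusted p = 9.34e-09), with 9.36% in length-matched lists and 14.2% for rotated peaks (permutation, adjusted p = 0.00959). Cytochrome P450 genes of families 2, 3 and 4, which oxidise drugs and steroids, were marked in 27 of 77 cases (35.1%; 46.1% ± 0.918 in the replicates), with 10361 bp in Cyp2b9, 9704 bp in Cyp3a16 and 9582 bp in Cyp3a57. Their odds ratio was 2.59 (Fisher's exact test, adjusted p = 0.000476), and the call ended against rotated peaks (permutation, adjusted p = 0.0911) and with wholly single-copy peaks (Fisher's exact test, adjusted p = 0.261). Olfactory receptors, the odorant receptors of the nose, were marked in 104 of 1092 cases (9.52%; 12.8% ± 2.07), with 4975 bp in Olfr398, 4458 bp in Olfr139 and 3572 bp in Olfr161. This was less often than other genes (odds ratio 0.489, Fisher's exact test, adjusted p = 6.47e-13) but 1.83 times the share of length-matched lists (random list permutation, adjusted p = 0.000686), and its difference from rotated peaks did not pass (permutation, adjusted p = 0.442). With the TSS window in place of the gene body the call turned: 56 receptors or 5.13% were marked, more often than other genes (odds ratio 2.34, Fisher's exact test, adjusted p = 5.87e-07).

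Among smaller families, Pramel genes of oocyte and testis were marked in 5 of 12 cases (45.8% ± 5.89 in the replicates, SD, n = 2; Fisher's exact test, adjusted p = 0.0631), with 4330 bp in Pramef12, 1496 bp in Pramef20 and 984 bp in Pramel5, and the list was higher than length-matched lists (random list permutation, adjusted p = 0.003) but not than rotated peaks (permutation, adjusted p = 0.0915). Pramel genes were called higher above the median fold (Fisher's exact test, adjusted p = 0.0126), for peaks overlapping both replicates' lists (0.023) and in TSS windows (odds ratio 13.6, adjusted p = 0.00883). Beta-defensins, secreted antimicrobial peptides, were marked in 3 of 42 cases (Fisher's exact test, adjusted p = 0.134), with 3831 bp in Defb33 and 1146 bp in Defb39. The replicates' own lists marked 16.7% ± 6.73 of beta-defensins (SD, n = 2). In TSS windows 5 were marked in the replicated list, more often than other genes (odds ratio 5.54, Fisher's exact test, adjusted p = 0.0096). Serpins, mostly protease inhibitors, were marked in 10 of 61 cases (Fisher's exact test, adjusted p = 1), with 4466 bp in Serpinb6d, 1533 bp in Serpina1b and 1039 bp in Serpinb6e. The replicates' own lists marked 33.6% ± 5.80 of serpins (SD, n = 2). Their odds ratio was 0.936, but 1.16 without replicate 1 and 1.74 without replicate 2, and the list was called in neither. Cancer-testis families were marked in 6 of 79 cases, less often than other genes (Fisher's exact test, adjusted p = 0.0384), but 73 members lie on the X, where few peaks were called. The call ended above the median fold (Fisher's exact test, adjusted p = 0.0756), at a −log10 q of at least 5 (0.0851), with 500 bp of peak (0.123) and against length-matched lists (permutation, 0.97), and against rotated peaks the ratio turned to 1.64 (permutation, adjusted p = 0.48). Magel2, which is also on the imprinted list and lies on chromosome 7, was covered over 88.6% of its body, and Rhox13 and Ssxb5 held 748 bp and 512 bp.

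Several lists of broadly expressed or lineage-restricted genes carried few or no replicated peaks. None was found in 110 keratin genes (Fisher's exact test, adjusted p = 5.57e-09), 83 ribosomal protein genes (7.92e-07), 67 histone genes (1.53e-05), 45 housekeeping genes (0.000588), 29 genes of other lineages such as liver, muscle and gut (0.012) or 23 forebrain and midbrain regulators (0.0384). Of 39 Hox genes, which set position along the body axis, 1 was marked (Fisher's exact test, adjusted p = 0.0179); it was Hoxa9, with 211 bp and no peak in replicate 2, named after its value was seen. The replicates' own lists marked 21.7% ± 6.15 of the forebrain and midbrain regulators, 12.8% of Hox genes each, 6.67% of housekeeping genes each, 10.3% of other-lineage genes each, 3.01% ± 0.852 of ribosomal protein genes, 2.27% ± 1.93 of keratin genes and 0.746% ± 1.06 of histone genes (SD, n = 2). Without replicate 1 the calls ended for the Hox (Fisher's exact test, adjusted p = 0.101), other-lineage (0.0903) and forebrain and midbrain lists (0.573), and without replicate 2 as well (0.101, 0.092 and 1). In the pooled list the other-lineage and the forebrain and midbrain calls ended (Fisher's exact test, adjusted p = 0.638 and 1), and at a −log10 q of at least 5 these, the Hox and the housekeeping calls did (0.17, 0.313, 0.0851 and 0.0688). Other-lineage, forebrain and midbrain, and Hox calls ended with 5 kb flanks (Fisher's exact test, adjusted p = 0.0766, 0.917 and 0.27) and with wholly single-copy peaks (0.0535, 0.109 and 0.1). The first 2 of these ended for peaks in both replicates' lists (Fisher's exact test, adjusted p = 0.0699 and 0.141) and with 500 bp of peak (0.122 and 0.152). These genes are mostly short, with median lengths from 0.539 kb for histone genes to 10.9 kb for housekeeping genes. Against length-matched lists only the keratin list stayed lower (permutation, adjusted p = 0.0277), and against rotated peaks only the housekeeping list did (permutation, adjusted p = 0.048).

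Genes of the tissue itself were not called higher or lower than other genes in the replicated list. No list for other cell types that the tissue could hold was called higher. Of those lists, only the forebrain and midbrain regulators, given above, were called lower. Hindbrain regulators were marked in 4 of 50 cases (16.0% ± 5.66 in the replicates, SD, n = 2; Fisher's exact test, adjusted p = 0.13): Pax5 with 984 bp, Pax7 with 899 bp, Pax3 with 317 bp and Lmx1a with 281 bp, all transcription factors of dorsal or isthmic patterning and none marked in its TSS window. They were called lower in the pooled list, with 9 marked (Fisher's exact test, adjusted p = 0.0279), and without replicate 1, with 6 marked (Fisher's exact test, adjusted p = 0.0399). Neural genes were marked in 5 of 34 cases (23.5% in each replicate; Fisher's exact test, adjusted p = 0.898): the synaptic genes Syt1 with 1626 bp and Snap25 with 482 bp but no peak in replicate 1, the neurofilament gene Nefm with 1577 bp, the progenitor gene Prom1 with 908 bp and the adhesion gene Ncam1 with 309 bp. Of the 28 genes of the H3K9 machinery, Atf7ip, a partner of the methyltransferase SETDB1, held 4020 bp in 6 peaks and Morc2a held 240 bp with no peak in replicate 1 (28.6% ± 5.05 in the replicates; Fisher's exact test, adjusted p = 0.253). In blood genes 1 of 22 was marked (adjusted p = 0.199 by Fisher's exact test), Gata1 with 286 bp, and without replicate 1 the list was called lower (adjusted p = 0.0277 by Fisher's exact test). In endothelial and microglial genes 5 of 18 were marked (adjusted p = 0.253 by Fisher's exact test), with 1530 bp in Flt1, 833 bp in Tek and 668 bp in Cx3cr1. In mesenchyme genes 3 of 17 were marked (adjusted p = 1 by Fisher's exact test), with 1372 bp in Runx2, 407 bp in Col2a1 and 301 bp in Prrx1. The replicates' own lists marked 35.3% ± 8.32 of the mesenchyme genes (SD, n = 2).

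Part of the replicated peaks lay in broad domains, some of them over gene clusters. Joined at 5 kb, they formed 38 domains of at least 50 kb with 2.75 Mb in all, of which 16 lay on chromosome 7, 5 on chromosome 4 and 4 on chromosome 18. The longest spanned 171 kb on chromosome 7 (17936222 to 18107474) with Ceacam11, Ceacam12 and Ceacam13, of a family of adhesion glycoproteins; 44.8% of its bases were under replicated peaks, 25% under peaks of replicate 1 and 38.8% under those of replicate 2. The next spanned 168 kb on chromosome 4 (121561745 to 121730164) with Gm12887, and 122 kb on chromosome 18 (37655584 to 37777702) with 18 gamma protocadherin genes, from Pcdhga1 to Pcdhga12. Then followed 88.1 kb on chromosome 7 (14512648 to 14600788) with the vomeronasal receptor gene Vmn1r90, and 84.9 kb on chromosome 18 (36896715 to 36981565) with Pcdha1 to Pcdha7. Random placement scatters the pieces of a broad region, so its longest domain of 29.6 kb is no test of these lengths. The number of domains was 61 without replicate 1, 31 without replicate 2, 123 in the pooled list, 15 for peaks overlapping both replicates' lists, 10 above the median fold, 9 at a −log10 q of at least 5, 2 joined at 1 kb and 172 at 10 kb. For peaks in both replicates, above the median fold, at the stricter q and joined at 1 kb, the longest lay in the gamma protocadherin genes instead (122, 119, 119 and 100.4 kb).

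Peaks in zinc finger and clustered protocadherin genes were also stronger than those in other genes. Their median fold enrichment was 3.41 over 713 peaks of zinc finger genes, against 2.98 in other protein-coding genes, and 3.85 over 214 peaks of protocadherin genes, against 3.03 (permutation, adjusted p = 8e-05 each, from the smallest unadjusted p possible, 1e-05). The permutation treats single peaks as independent. All protocadherin peaks lie in the cluster on chromosome 18, and a broad region can be divided into many peaks, which these p-values do not allow for. No other list passed by fold in the replicated list; imprinted genes had 3.15 against 3.04 (permutation, adjusted p = 0.398) and germline genes 3.19 against 3.03 (permutation, adjusted p = 0.36). Imprinted genes did pass by −log10 p (permutation, adjusted p = 0.0421), and in the pooled list germline and vomeronasal receptor genes did by fold (permutation, adjusted p = 7.67e-05 and 0.005). The strongest peak by fold enrichment, 12.6, lay on chromosome 6 (30955456 to 30959116) and covered all of Klf14, a single-exon gene for a Krüppel-like transcription factor that is known as imprinted but was not on the fixed list, with 10.1 in replicate 1 and 12.8 in replicate 2. Zfp810 on chromosome 9 held a peak of 8.46 and Zfp513 on chromosome 5 one of 7.76. Pcdha1 to Pcdha9 shared a peak of 7.58 (chromosome 18, 36999621 to 37000593) with Gm42416, Gm37013 and Gm37388, which span the cluster. These folds are the authors' values and come without an error for single peaks.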

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

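No test was run on the peaks in this part; the values were counted after the other results were seen. Outside the assembled chromosomes, the replicated list held 262 H3K9me3 peaks on 25 unplaced and unlocalised scaffolds, which are given here because no comparison used them. The files hold no control list, so there is no background level to set this count against. These peaks covered 256 kb and made up 0.873% of the list, with 376 scaffold peaks in replicate 1 and 324 in replicate 2, and 58 of the replicated ones lay on a single scaffold. Their median −log10 p was 16.8 against 7.42 on the chromosomes, at a median fold enrichment of 3.17 against 3.03. Genes on these scaffolds were not analysed here.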

How the results depend on the processing

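Peaks overlapping both replicates' lists and mostly or wholly single-copy peaks were chosen after the results were seen; the other alternatives were planned. No paired analysis was possible because there is 1 group. The overlap of the replicates, the 3′ position in zinc finger genes, the GC difference and the marking calls of the protocadherin, vomeronasal, imprinted and germline lists kept their direction and their side of the threshold under every alternative run. For the results below the cause was not tested, except that stricter thresholds leave fewer peaks and pooled lists more. The share of replicated peaks found in both replicates was 37.1% at 50% overlap and 63.1% at 1 bp. At a −log10 q of at least 5 it was 59.0% at 50% overlap and 84.9% at 1 bp. Chromosome 7 stood at 2.72 times the autosome median in the pooled list, 3.99 above the median fold, 4.01 at the stricter q, 3.78 for peaks in both replicates and 2.87 to 2.87 leaving out a replicate. The X stood at 0.510 in the pooled list and 0.332 to 0.540 leaving out a replicate. The TSS share over rotated was 0.698 to 0.932 and the exon share 1.11 to 1.28 leaving out a replicate, and the exon share 1.02 in the pooled list. Marked genes numbered 7482 in the pooled list, 2342 above the median fold, 1971 at the stricter q, 5659 to 5810 leaving out a replicate, 2518 with at least 500 bp of peak and 526 in TSS windows. Lists marked less often numbered 4 at the stricter q, 0 in TSS windows, 1 by length-matched lists and 1 by rotation, against 9. In TSS windows the zinc finger odds ratio was 1.52, and olfactory (2.34), cancer-testis (1.06), defensin (5.54) and Hox genes (1.07) reversed, the olfactory and defensin lists past the threshold. Forebrain and midbrain regulators reversed in the pooled list (1.03) and without replicate 2 (0.583 to 1.01 leaving out a replicate), cancer-testis genes on autosomes (2.30) and against rotation (1.64), and olfactory genes against length-matched lists (1.83) and rotation (1.42). Domains of at least 50 kb numbered 123 in the pooled list, 10 above the median fold, 9 at the stricter q, 31 to 61 leaving out a replicate, 15 for peaks in both replicates, 2 joined at 1 kb and 172 at 10 kb. The longest was 244 kb in the pooled list, 119 kb above the median fold and at the stricter q, 122 kb for peaks in both replicates, 100.4 kb at 1 kb and 303 kb at 10 kb, and 143 to 227 kb leaving out a replicate. Lists with stronger peaks numbered 4 in the pooled list, where germline and vomeronasal genes were added, and 3 by −log10 p, where imprinted genes were, against 2. The depth is not in the lists, so peaks missing from 1 replicate can be weak sites below its threshold.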

Other observations

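The gene families by symbol stem, the tests of peak position, the test of X peaks near TSSs, the filters for mostly and wholly single-copy peaks, the comparison of X peaks with list length and the test of fold enrichment among the smallest p were chosen after the results were seen; the other tests below were set before their results were seen. Beyond the fixed lists, protein-coding genes were grouped into families by symbol stem. Among 359 families of at least 8 members, 19 were marked more often than other genes, 13 of them wholly or mostly outside the fixed lists, and 3 of these also exceeded length-matched lists after adjustment. Nlrp genes, a family of innate immune sensors of which several act in the oocyte and Nlrp5 is on the germline list, were marked in 11 of 17 cases (64.7%; odds ratio 8.78, Fisher's exact test, adjusted p = 0.000596). Klra genes, the Ly49 receptors of natural killer cells, were marked in 7 of 11 cases (63.6%; odds ratio 8.37, Fisher's exact test, adjusted p = 0.0136), against 11.9% in length-matched lists and 13% for rotated peaks. Ceacam adhesion genes, many of them expressed in the placenta, were marked in 8 of 15 cases (53.3%; Fisher's exact test, adjusted p = 0.0264). Skint genes of skin and thymus were marked in 9 of 11 cases (81.8%; Fisher's exact test, adjusted p = 0.000217) but missed the length-matched threshold (random list permutation, adjusted p = 0.0538). Unadjusted rotation permutation p-values were 0.024 for Nlrp, 0.038 for Klra, 0.0839 for Ceacam and 0.0659 for Skint. Long genes such as the dynein heavy chains, Dnah, with 11 of 15 marked, stood near their length-matched share of 60.4%.

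TSS windows were marked in a larger share of germline and imprinted genes than of zinc finger genes. In germline genes 15 of 63 were marked there (23.8%; 26.2% ± 1.12 in the replicates, SD, n = 2), among them Dazl, Ddx4, Mael, Sycp1, Sycp2, Sycp3, Stag3, Sohlh2, Boll and Taf7l, and 13 of the 15 were marked there in both replicates. In imprinted genes 15 of 53 were (28.3%), 14 of them in both replicates, among them Peg3, Peg10, Peg12, Sgce, Nnat, Nap1l5, Zrsr1, Snurf, Magel2, Mkrn3 and Cdkn1c. In zinc finger genes 15 of 419 were (3.58%), a lower share than in germline genes (Fisher's exact test, p = 3.77e-07) and in imprinted genes (Fisher's exact test, p = 3.6e-08). These tests treat genes as independent, although some windows overlap, such as those of Sgce and Peg10. Last exons were marked in 27.4% of zinc finger genes, 15.9% of imprinted genes and 1.64% of germline genes with more than 1 exon.

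The first pattern weighed is the frequent marking of zinc finger genes, for which the design gives no biological contrast, so no biological explanation was tested. Repeated sequence as the whole cause is argued against: with only the 15006 wholly single-copy peaks, 50.4% of the list, the odds ratio was 2.87 (Fisher's exact test, adjusted p = 5.18e-18). With the mostly single-copy peaks the odds ratio was 3.19. These made up 98.2% of the list, so that filter could hardly have changed the value. Gene length is argued against too, since the list was marked 3.03 times as often as length-matched lists. Peaks in zinc finger genes had on average 86.3% single-copy sequence, against 90.3% over all peaks and 82.4% when rotated. Near-identical copies that differ by a base were not counted, and the authors' alignment and control, which are not given in the sources used here, stay open.

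The second pattern is that replicate 1 had more X peaks than replicate 2, 1724 or 3.68% of its list against 1389 or 2.34%. In counts the excess lay among weaker peaks. At a −log10 q below 1 replicates 1 and 2 had 459 and 209 X peaks, from 1 to 2 774 and 713, and from 2 to 3 319 and 257. From 3 to 5 they had 122 and 153, and at 5 or more 50 and 57. A longer list in replicate 1 is argued against, as its list was the shorter one, at 0.791 times the peaks of replicate 2. The list lengths were known before this comparison was chosen, and they do not bear on how weak the calls are. A q below 0.05 was reached by 58.1% of the peaks of replicate 1 and 73.2% of those of replicate 2. Calls scattered evenly over the X are argued against as well, because X peaks found in replicate 1 only had a variance-to-mean ratio per Mb of 9.81. The autosomes ranged from 2.29 to 24.5, but for peaks that were likewise found in replicate 1 only. The ratio therefore cannot tell background calls that cluster from signal. A different share of male and female embryos in the pools cannot be told apart, since the Y held only 14 and 16 peaks (Fisher's exact test, p = 0.855). The further file behind the list of replicate 2 may matter and was not tested; X peaks within TSS windows were 9.86% in replicate 1 and 5.11% in replicate 2 (Fisher's exact test, p = 7.09e-07).

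The last pattern is the 20 replicated peaks with the smallest p, of which 13 lie within 1 Mb of another, such as those at Tmem267 on chromosome 13, Sfi1 and Drg1 on chromosome 11 and Gm21887 on the X. High fold enrichment alone is argued against, because only 8 of the 20 were among the top 1% of peaks by fold, at 5.16 or more; the smallest p belonged to a peak of 5.03 on chromosome 13 (119597593 to 119598279). Repeated sequence cannot be told apart as a source for the 20 as a set: the median single-copy share was 86.4% against 100% over all peaks, 17 of the 20 were mostly single-copy, and the value lies between the bounds set before. The mean share was 73.6% against 90.3% over all peaks. The X peaks at Gm21887 and Mid1 had a single-copy share of 0%. Copies that the assembly lacks were not tested and could raise coverage at such places. The design holds no group that tests a biological explanation.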
